A study of Brassica oleracea with 24 samples.

How the data were processed

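The series holds 24 RNA-seq libraries from roots of 2 Brassica oleracea accessions, 3 for each combination of accession, phosphate supply and zinc supply. Seedlings germinated on moist filter paper were moved to hydroponic buckets and grown for 2 weeks in a glasshouse, with buckets placed at random on a single bench, per the labels' protocols. RNA was extracted with Trizol, column-purified with a DNase step, and sequenced by a provider as short single-end reads. Reads were aligned to the Ensembl Plants B. oleracea reference, per the labels' protocols; HISAT, Bowtie2 and RSEM are named in the submitters' processing notes, with no versions or settings. Whether the libraries kept strand, and the trimming and filtering settings, are not given in the sources used here.

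The authors deposited 1 table per library with a gene ID, transcript IDs, a length, an expected count and an FPKM for each gene. The deposited expected counts are estimates of reads per gene, as RSEM makes them: between 48.69% and 52.01% of values per library differed from a whole number by more than 0.005. Reads that match several near-identical genes are shared between them by such an estimate, and Brassica genomes hold many close gene copies, so counts of single copies can be uncertain. The deposited FPKM values are scaled to gene length and library depth by the authors, as the column name states per the file headers, and the lowest value listed was 0.01; a gene not listed in a library was taken as 0. Of the lengths, 99.8% are multiples of 3, so they are coding lengths. The tables hold 50474 gene IDs in all, 28247 of them listed in every library. None of the IDs (0 of 50474) matched the 53125 genes of the RefSeq name table supplied for the species, and the files pair IDs with no names. The 26 gene lists fixed at the outset, which need names or descriptions, could therefore not be applied, and no shift of any of these lists was tested; cell type and tissue markers were among them. No coordinates are given for the same reason.

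Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which left 31975, and counts were scaled by TMM. One model with a mean for each of the 8 groups was fitted to all 24 libraries with edgeR 4.0.16 (R 4.3.3), and each comparison was a contrast tested with the quasi-likelihood test (glmQLFit, glmQLFTest) and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.377. Standard errors of log2 fold changes were derived from the fold change and its F statistic and are approximate. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. A fold against a group with 0 counts in all 3 libraries is a lower bound against a floor of 3 counts over the group; a group with 1 to 3 counts is given as a ratio of pooled counts with an exact 95% interval, which covers counting error only. Log2 fold changes are low against high supply, or F103 against C6.

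The naming rule asked for genes with a name or description and, where no source names genes, for 2 IDs that rose and 2 that fell per comparison. The IDs in the text are those with the largest change among genes past the threshold whose 3 libraries of one group all lay above the 3 of the other and whose mean was at least 1 CPM, or those with the smallest adjusted p for interactions; chance alone gives such separation of 3 from 3 libraries for 10% of genes. Gene groups were made after seeing the data, from the calls of one comparison, and followed in libraries that had no part in choosing them. Groups were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and with an estimated correlation, adjusted over 35 tests. Of 30 calls with the preset value, 23 held with an estimated correlation, and the text gives the latter. Overlaps between lists were tested with a one-sided Fisher's exact test over genes, adjusted over 30 tests; genes are not independent, so these p-values are too small. The lists compared also share 1 estimate of spread per gene, so they are not fully independent of each other.

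Counts simulated from these libraries, with 100 genes changed 2-fold and 100 changed 4-fold among 31975, were used to test the procedure. They were drawn with edgeR's estimates of spread around 1 mean level per gene, without mixed or outlying libraries. For low against high zinc in C6 at high phosphate, edgeR recovered 14 and 50 of them with 1 false call, DESeq2 24 and 68 with 36 false calls, and limma 16 and 52 with 4 false calls. Replicate libraries of a group were compared over genes with at least 20 counts in both: the mean chi-square per gene over the 24 pairs lay between 10.6 and 217, far above counting noise, so no library was a copy of another of its group. Over all 24 libraries, 0 had rounded counts identical to those of another. Genes detected almost solely in F103 were those with at least 1 CPM in 8 or more F103 libraries and under 0.1 CPM in 10 or more C6 libraries (106 genes, 54 of them with a median of at least 3 CPM); genes detected almost solely in C6 were those with at least 1 CPM in 10 or more C6 libraries and under 0.1 CPM in 8 or more F103 libraries (38 genes, 24 of them with a median of at least 2 CPM). Ratios to the accession's median from simulated mixtures of 0.1, 0.2 and 0.5 came out at 0.101, 0.207 and 0.497. The F103-only genes are near 0 in C6 by choice and each mixture used the same F103 median, so these ratios follow by construction. They check the calculation only, since differences between F103 libraries were not simulated.

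The samples, groups, tests, gene lists, naming rule and the following alternatives were chosen before the data were examined: DESeq2's size factors in edgeR, no low-count filter, a filter of at least 1 CPM in every library of a group, the DESeq2 1.42.0 Wald test, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) over genes with an FPKM of at least 1 in 3 or more libraries, robust dispersion, only the libraries compared, and leaving out each library in turn. Fold changes from the FPKM fits are on the log2(value + pseudocount) scale, which understates low genes. Fits without 4 doubted libraries and with 3 surrogate variables (sva 3.50.0) were added after seeing the data.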

Results

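RNA from roots of Brassica oleracea, the species of cabbage, kale and broccoli, was sequenced in 24 libraries. The plants belonged to 2 accessions, named C6 and F103, and grew for 2 weeks in aerated nutrient solution. The solution held either 0.25 mM phosphate (called high phosphate here) or 0.025 mM (low), and either 1 µM zinc sulfate (high zinc) or none added (low zinc). Each of the 8 combinations of accession, phosphate and zinc had 3 libraries. Phosphate and zinc are both taken up by roots, and the study asked how roots respond early to zinc supply when phosphorus is sufficient or not. The deposited counts per library summed to between 8707405 and 9696889, with a median of 9231978, so depth differed little between libraries. Between 35665 and 39148 genes were listed per library, and 31975 genes entered the tests. No source used here pairs the gene IDs of these files with gene names, so genes are given by ID and described by how they responded. The labels do not say whether replicate libraries came from separate buckets, and p-values measure only the spread between these libraries. Library titles hold a number that all 3 libraries of a group share and that differs between groups. Its meaning is not given. If it marks a bucket, effects of bucket and of treatment cannot be told apart.

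Libraries separated first by accession. The first principal component of log2 CPM (counts scaled to a common library size) held 33.8% of the variance and the second 18.6%. Of the 12 F103 libraries, 3 correlated more closely with C6 libraries than with F103 libraries. They were replicate 2 at low phosphate and low zinc (median r over genes 0.924 with C6 against 0.903 with F103), replicate 2 at high phosphate and low zinc (0.916 against 0.908) and replicate 3 at high phosphate and high zinc (0.925 against 0.902). Over 54 genes detected almost solely in F103, the median ratio to the usual F103 level was 0.187, 0.273 and 0.271 in these 3 libraries, between 0.863 and 1.187 in the other 9 and 0 in every C6 library. Over 24 genes detected almost solely in C6, the same 3 libraries stood at 0.408, 0.567 and 0.498 of the C6 level, and each of the other 9 at 0. One C6 library, replicate 3 at low phosphate and high zinc, lay far from all others. It had 26151 genes at an FPKM of 1 or more against 29200 to 30495 elsewhere. It held 17.12% of its counts in its 50 most abundant genes (95% Wilson interval 17.09% to 17.14%, which covers counting error only) against 7.51% to 13.32%. All 24 libraries stayed in the tests, and each count is also given without these 4 libraries, an alternative chosen after seeing the data.

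**Figure D1:**
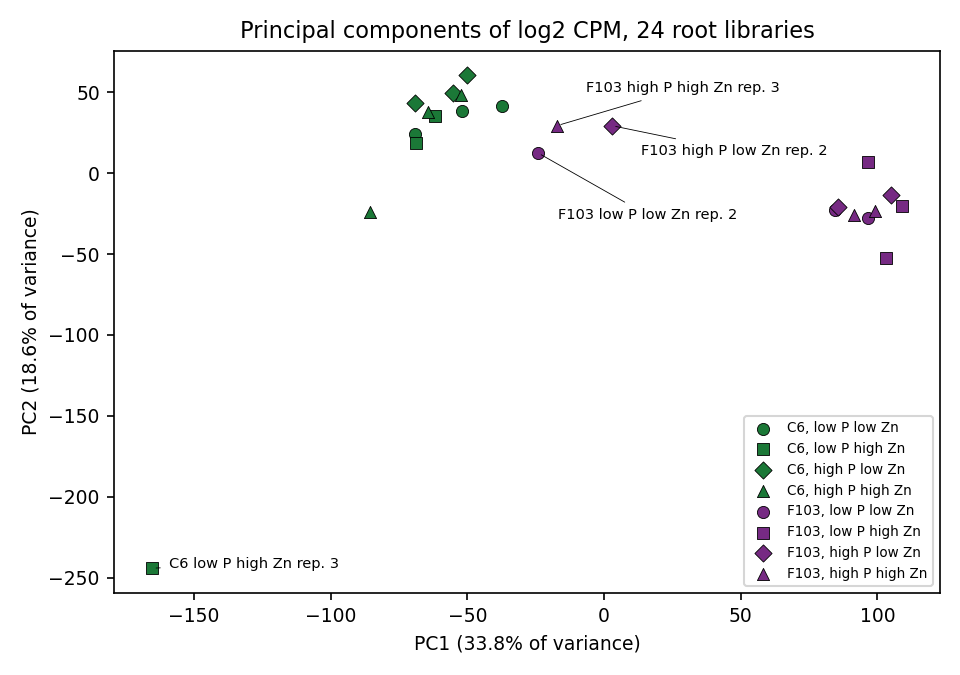
Scores of the 24 libraries on the first (33.8% of variance) and second (18.6%) principal components of log2 CPM, with colour for accession and marker for treatment. Of the F103 libraries, 3 lie between the accessions, and replicate 3 of C6 at low phosphate and high zinc lies apart on the second axis.

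**Figure D2:**
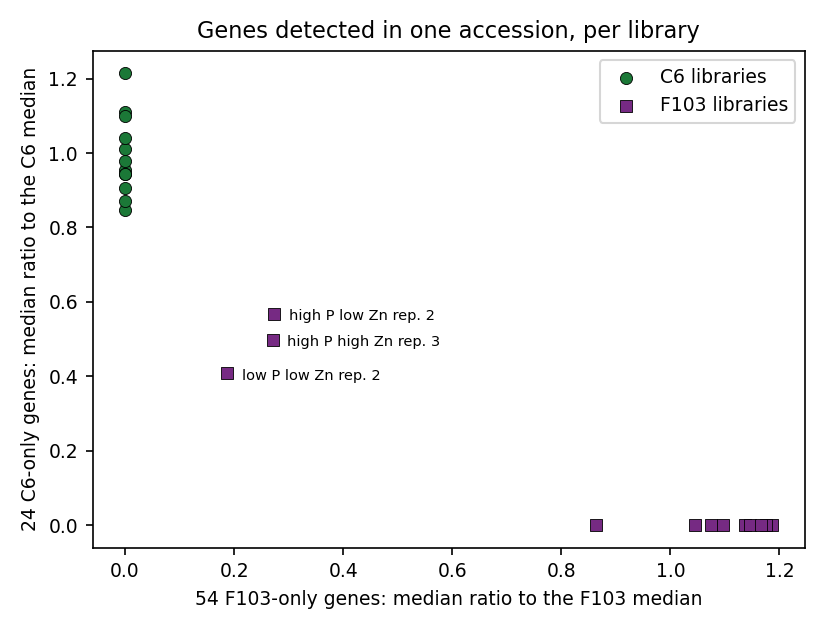
Each point is a library; the horizontal axis gives the median ratio to the F103 median over 54 genes detected almost solely in F103, and the vertical axis the median ratio to the C6 median over 24 genes detected almost solely in C6. The 3 named F103 libraries lie between 0.187 and 0.273 on the first and between 0.408 and 0.567 on the second.

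In C6 roots at low zinc, low phosphate changed 201 genes, of which 72.1% rose and 56 fell. Bo4g195920 rose from 0.423 ± 0.262 to 93.9 ± 54.4 CPM (SD, n = 3 each), a log2 fold change of 7.74 ± 0.82 (SE; edgeR, adjusted p = 4.6e-05). Bo4g017370 had 1 count in total at high phosphate and 32.1 ± 24.3 CPM (SD, n = 3) at low phosphate, a ratio of 915 with a 95% counting interval of 164 to 36200 (edgeR, adjusted p = 0.00052). Bo5g008770 fell at least 87.9-fold, from 9.75 ± 5.94 CPM (SD, n = 3) to 0 counts in all 3 libraries (edgeR, adjusted p = 0.0081). Bo01941s010 fell at least 35.3-fold, from 3.84 ± 1.48 CPM (SD, n = 3) to 0 counts (edgeR, adjusted p = 0.038), and lost its call when any of the 6 libraries was left out. The total was 573 genes (370 higher, 203 lower) without the 4 doubted libraries. On log2(FPKM + 1), limma called 251 genes, 56.6% of them higher. Leaving out replicates 1, 2 and 3 of the high phosphate group gave 90, 75 and 108 genes. Leaving out replicate 2 of the low phosphate group gave 110 genes, and leaving out replicate 1 gave 0.351% of the genes tested, against 0.629% with all libraries.

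In C6 roots at high zinc, low phosphate raised 207 genes and lowered 78. Of these, 90 of the raised genes and 13 of the lowered genes had also been called at low zinc, in libraries shared with neither group. Independent lists would share 0.939 and 0.137 (Fisher's exact test, adjusted p = 2.1e-166 and 1.4e-22). Bo01196s010 had 1 count in total at high phosphate and 24.3 ± 13.3 CPM (SD, n = 3) at low phosphate, a ratio of 745 with a 95% counting interval of 133 to 29500 (edgeR, adjusted p = 5.9e-05). Bo3g083970 rose at least 60.2-fold, from 0 counts to 5.72 ± 4.18 CPM (SD, n = 3; edgeR, adjusted p = 0.0073). Bo9g002210 fell from 14.6 ± 8.43 CPM (SD, n = 3) to 0 counts, a log2 change of at least 6.93 in size (edgeR, adjusted p = 0.029), and had no count in any F103 library. Bo2g026760 fell from 16.1 ± 11.2 CPM to 1 count in total, a ratio of 399 with a 95% counting interval of 71.2 to 15800 (edgeR, adjusted p = 5.9e-05). One of the libraries compared is the C6 library that lay apart. The fit without the 4 doubted libraries gave 308 higher and 117 lower, 194 of the 425 being among the 285. On log2(FPKM + 1) the balance turned, with 39.8% of 284 genes higher (limma), against 72.6% of the 285. That fit applies no TMM factor, which was 0.721 for the C6 library that lay apart and raised its levels in the reported fit. A fit of only the libraries compared called 0 genes (edgeR), while DESeq2 on all libraries called 1076. In the former, 1410 genes had an unadjusted p under 0.05, where chance alone gives a share of about 0.05 of the genes tested. The call of Bo9g002210 was lost in 2 of the 6 fits that left out 1 library. The count was 921 or 482 without replicate 1 or 2 of the low phosphate group. Without replicate 2 of the high phosphate group it was 165, and without replicate 3 it was 0.345% of the genes tested, against 0.891% with all libraries.

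In F103 roots at low zinc, low phosphate raised 50 genes and lowered 3. Bo4g017370 rose at least 91.9-fold, from 0 counts to 9.7 ± 4.89 CPM (SD, n = 3; edgeR, adjusted p = 0.0059), and Bo4g195920 rose from 0.175 ± 0.112 to 37.3 ± 30.1 CPM (SD, n = 3 each), a log2 fold change of 7.60 ± 0.88 (SE; edgeR, adjusted p = 0.00026). Both genes also led the C6 response at low zinc, and 42 of the 50 raised genes were called in C6 at the same zinc supply, where independent lists would share 0.227 (Fisher's exact test, adjusted p = 1e-92). Among the lowered genes, Bo1g073610 fell by 1.56 ± 0.29 on the log2 scale (SE; edgeR, adjusted p = 0.028) and Bo3g107060 by 1.52 ± 0.25 (SE; edgeR, adjusted p = 0.0091). Each group holds one F103 library with a low level of F103-only genes. In the fit without the 4 doubted libraries 37 genes were higher and 2 lower, and 28 of these 39 were among the 53. Neither named lowered gene passed there (adjusted p = 0.11 for Bo1g073610 and 0.061 for Bo3g107060, edgeR), and their calls were lost in 5 and 3 of the 6 fits that left out 1 library, that of Bo4g017370 in 1. A fit of only the libraries compared called 19 genes, 13 of them among the 53, and no gene named here. The count was 31 without replicate 2 of the low phosphate group and 23, 18 and 29 without replicates 1, 2 and 3 of the high phosphate group.

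In F103 roots at high zinc, low phosphate raised 216 genes and lowered 44. The raised genes included 48 of the 50 raised at low zinc, and 53.2% of the 216 were also raised in C6 at high zinc. Independent lists would share 0.338 and 1.40 genes (Fisher's exact test, adjusted p = 1.2e-103 and 2.8e-205). Bo9g021520 rose at least 163-fold, from 0 counts to 16.5 ± 6.54 CPM (SD, n = 3; edgeR, adjusted p = 0.00055), and had at most 2 counts in any C6 group. Bo7g093110 rose at least 73.7-fold, to 7.40 ± 6.08 CPM (SD, n = 3; edgeR, adjusted p = 0.018). Bo5g008780 fell by 5.82 ± 1.18 on the log2 scale (SE; edgeR, adjusted p = 0.016), from 11.2 ± 11.8 to 0.184 ± 0.124 CPM (SD, n = 3 each). Bo9g088320 fell to 1 count in total, from 3.61 ± 2.91 CPM (SD, n = 3), a ratio of 96.0 with a 95% counting interval of 16.9 to 3830 (edgeR, adjusted p = 0.031). The high phosphate group holds an F103 library with a low level of F103-only genes. In C6 at high phosphate and high zinc Bo5g008780 stood at 57.6 ± 31.8 CPM (SD, n = 3), so that library may have raised its F103 level. Its call held without the 4 doubted libraries (edgeR, adjusted p = 0.035). In that fit 309 genes were higher and 79 lower, with 219 of these 388 among the 260. A fit of only the libraries compared called 468 genes, 202 of them among the 260. Calls were lost in 4, 4 and 5 of the 6 fits that left out 1 library for Bo7g093110, Bo5g008780 and Bo9g088320. The count was 170 without replicate 2 of the low phosphate group, and 172 and 144 without replicates 2 and 3 of the high phosphate group.

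Across both accessions and both zinc levels, 34 genes were raised by low phosphate in all 4 comparisons and none was lowered in all 4 (edgeR, all libraries). Their median log2 fold change was 3.33 and 3.56 in C6 at low and high zinc, and 2.92 and 3.61 in F103. The response was followed across accessions in libraries outside the comparisons that chose the genes. All libraries shared 1 estimate of spread per gene, so the calls in different comparisons are not fully independent. The 90 genes raised in C6 at both zinc levels had higher fitted values under low phosphate in F103 for all 90 at both zinc levels, with a median log2 fold change of 1.58 at low zinc (34 called) and 2.40 at high zinc (79 called). The camera test gave an adjusted p = 2.2e-07 with an estimated correlation at low zinc and an adjusted p = 6.4e-07 with an estimated correlation at high zinc. The 48 genes raised in F103 at both zinc levels had medians of 2.89 (42 called) and 2.87 (36 called) in C6 at low and high zinc, with camera adjusted p = 7e-06 and 6.6e-05 with an estimated correlation. The 13 genes lowered in C6 at both zinc levels had medians of -0.93 (none called) and -1.50 (2 called) in F103, with camera adjusted p = 0.0017 and 0.0038 with an estimated correlation. In every library the mean level of the genes chosen in the other accession lay on the side of its phosphate label. Of the F103 groups, 3 hold a library with a low level of F103-only genes. No median of these gene groups moved by more than the SD of its level between replicates when the 4 doubted libraries were left out. Without the 4 doubted libraries 33 genes were raised in all 4 comparisons, 24 of them among the 34. The number was 67 without the C6 library that lay apart, and 15, 18 and 21 without replicates 2, 1 and 3 of F103 at high phosphate and low zinc. DESeq2 gave 77 raised and 1 lowered in all 4, and fits of only the libraries compared gave 0 and 0. With 3 surrogate variables edgeR lowered 2 genes in all 4 and raised 3.03 times as many as the 34, which were all among them. One gene was lowered in all 4 without replicate 2 of C6 at low phosphate and high zinc.

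**Figure D3:**
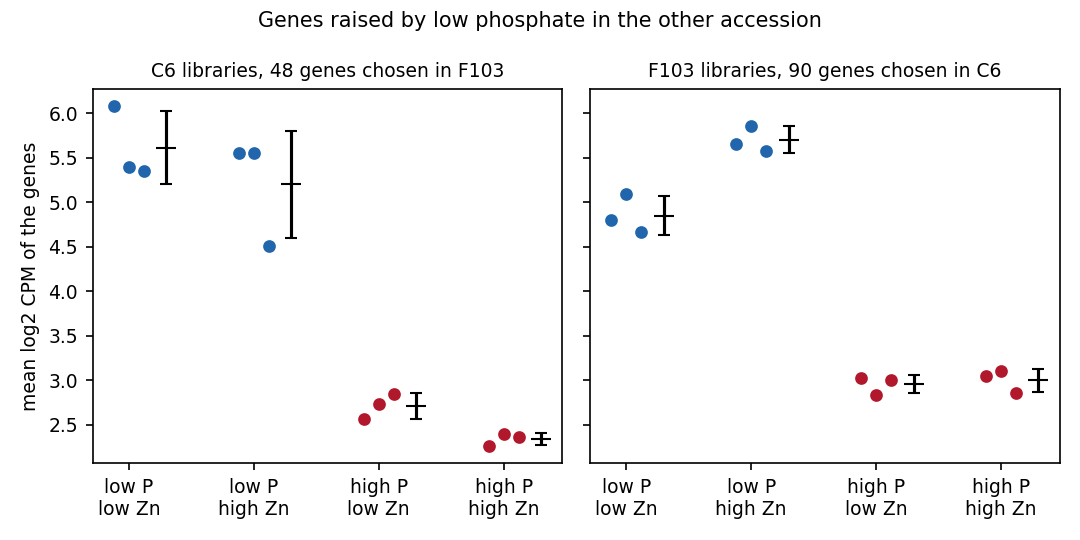
Mean log2 CPM per library (points), with group mean and SD (black, n = 3), of 48 genes raised by low phosphate in F103, shown in C6, and of 90 genes raised by low phosphate in C6, shown in F103. Low phosphate libraries (blue) lie between 4.51 and 6.08 in C6 and between 4.66 and 5.86 in F103, above all high phosphate libraries (red), which reach 2.85 and 3.10.

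In C6 roots at high phosphate, low zinc raised 56 genes and lowered 6. Bo9g043610 rose at least 133-fold, from 0 counts to 13.7 ± 3.04 CPM (SD, n = 3; edgeR, adjusted p = 0.02), and Bo1g158950 at least 82.9-fold, from 0 counts to 8.69 ± 6.04 CPM (SD, n = 3; edgeR, adjusted p = 0.003). Bo2g026760, which low phosphate lowered in C6 at high zinc, fell by 5.07 ± 0.72 on the log2 scale (SE; edgeR, adjusted p = 0.0016). Its level went from 16.1 ± 11.2 to 0.468 ± 0.178 CPM (SD, n = 3 each). Both calls of this gene rest on the same high phosphate, high zinc libraries, the only C6 group where its mean was above 0.468 CPM. Bo2g006650 fell by 4.32 ± 0.85 (SE; edgeR, adjusted p = 0.033), a call lost in 5 of the 6 fits that left out 1 library. The call of Bo9g043610 was lost in 4 of these fits, and a fit of only the libraries compared lost those of Bo1g158950 and Bo2g006650. Without the 4 doubted libraries 117 genes were higher and 26 lower, and all 62 were among these 143. The count was 36 without replicate 3 at low zinc, and 30, 38 and 30 without replicates 1, 2 and 3 at high zinc.

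In C6 roots at low phosphate, low zinc raised 28 genes and lowered 23. The raised genes included 16 of the 56 raised at high phosphate, where independent lists would share 0.049 (Fisher's exact test, adjusted p = 5.5e-38). Bo1g097950 rose from 3.06 ± 2.39 to 269 ± 298 CPM (SD, n = 3 each), a log2 fold change of 6.44 ± 1.15 (SE; edgeR, adjusted p = 0.044), and Bo1g053110 rose by 6.92 ± 1.15 (SE; edgeR, adjusted p = 0.047), to 20.6 ± 11.3 CPM (SD, n = 3). Bo2g064160 fell by 6.49 ± 0.87 on the log2 scale (SE; edgeR, adjusted p = 0.014), and Bo8g095480 fell at least 24.9-fold, from 2.77 ± 0.582 CPM (SD, n = 3) to 0 counts (edgeR, adjusted p = 0.044). The high zinc group holds the C6 library that lay apart: without it 4 genes were called. Without the 4 doubted libraries 2 were called, of which 1 was among the 51. Of the genes named here only Bo2g064160 stayed past the threshold without these 4 (adjusted p = 0.0088, edgeR). A fit of only the libraries compared called 0 genes (edgeR), while DESeq2 on all libraries called 1021. In the former, 1341 genes had an unadjusted p under 0.05, where chance alone gives a share of about 0.05 of the genes tested. Calls were lost in 2 and 3 of the 6 fits that left out 1 library for Bo1g097950 and Bo1g053110, and in 1 and 3 for Bo2g064160 and Bo8g095480. The count was 15, 0 and 351 without replicates 1, 2 and 3 at low zinc, and 1002 and 631 without replicates 1 and 2 at high zinc. It was 107 higher with 31 lower on log2(FPKM + 1) (limma).

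In F103 roots at high phosphate, low zinc raised 10 genes and lowered none. All 10 were among the 56 raised in C6 at the same phosphate supply, where independent lists would share 0.0175 (Fisher's exact test, adjusted p = 2.8e-28). Bo3g017600 rose from 1.51 ± 1.59 to 38.2 ± 3.47 CPM (SD, n = 3 each), a log2 fold change of 4.64 ± 0.66 (SE; edgeR, adjusted p = 0.015), and Bo1g005360 rose by 4.58 ± 0.79 (SE; edgeR, adjusted p = 0.038). In C6 at high phosphate Bo3g017600 stood at 136 ± 6.54 CPM at low zinc and 2.99 ± 2.80 CPM at high zinc (SD, n = 3 each). Each group holds one F103 library with a low level of F103-only genes. Without the 4 doubted libraries 3 genes were called, 2 of them among the 10, and neither named gene passed (adjusted p = 0.062 and 0.12, edgeR). A fit of only the libraries compared called 1 gene, which was not among the 10. Leaving out 1 library lost the call of Bo3g017600 in 2 of 6 fits and that of Bo1g005360 in 5. The count was 2 and 3 without replicates 1 and 2 at low zinc, and 19, 0 and 0 without replicates 1, 2 and 3 at high zinc.

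In F103 roots at low phosphate, no gene passed the threshold between low and high zinc in edgeR, while DESeq2 called 127. In edgeR 1895 genes had an unadjusted p under 0.05, where chance alone gives a share of about 0.05 of the 31975 tested. The genes that responded to zinc elsewhere were nevertheless shifted here. The 10 genes raised in F103 at high phosphate had a median log2 fold change of 2.28, all 10 positive, and all 10 passed when adjusted over the list alone (camera, adjusted p = 0.00046 with an estimated correlation). The 56 genes raised in C6 at high phosphate had a median of 1.68, or 1.40 with the 2 genes that had no count in a group set to their bound, and 43 were higher and 3 lower when adjusted over the list alone (camera, adjusted p = 0.00037 with an estimated correlation). These gene groups were chosen from other libraries of the same experiment after the data were seen. There were 22 calls without the 4 doubted libraries and 8 in a fit of only the libraries compared.

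The zinc response was followed across accessions in the same way as the phosphate response. The 56 genes raised by low zinc in C6 at high phosphate had a median log2 fold change of 1.69 in C6 at low phosphate. Of these, 16 were called there (camera, adjusted p = 0.0028 with an estimated correlation). In F103 at high phosphate the median of the 56 was 2.34, or 2.13 with 1 gene at 0 counts in a group set to its bound. There 10 were called (camera, adjusted p = 2.6e-05 with an estimated correlation). The 10 genes raised in F103 had medians of 4.60 (10 called) and 2.38 (7 called) in C6 at high and low phosphate, with camera adjusted p = 7e-06 and 0.0044 with an estimated correlation. In every library the mean level of the genes chosen in the other accession lay on the side of its zinc label. In F103 at high phosphate each group holds a library with a low level of F103-only genes, and the 10 genes were chosen with these included. The other libraries of these groups stood at 5.38 and 4.97 log2 CPM at low zinc and at 3.62 and 2.35 at high zinc for the 56 genes. Without the 4 doubted libraries no median of these gene groups moved by more than the SD of its level between replicates.

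**Figure D4:**
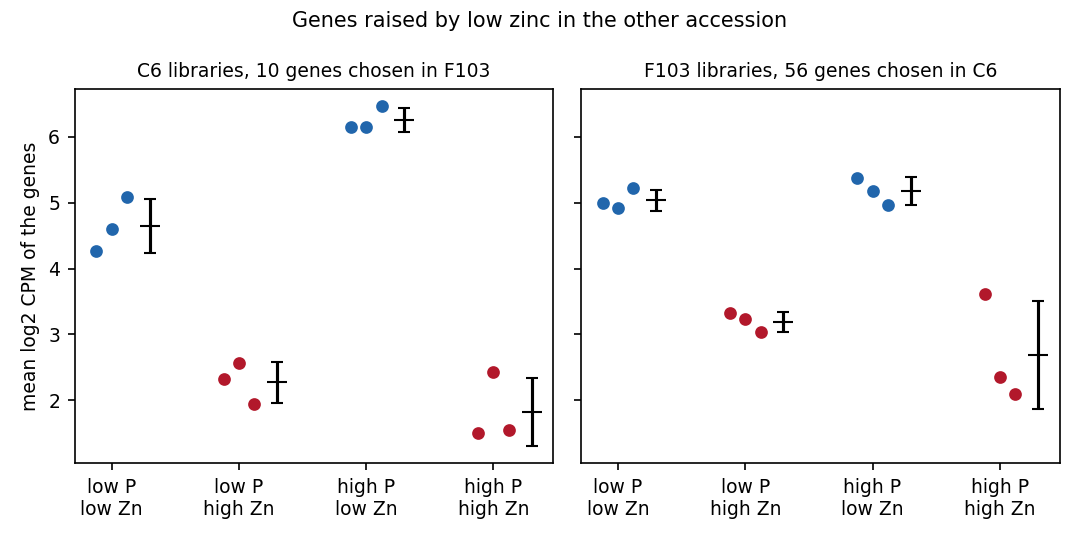
Mean log2 CPM per library (points), with group mean and SD (black, n = 3), of 10 genes raised by low zinc in F103, shown in C6, and of 56 genes raised by low zinc in C6, shown in F103. Low zinc libraries (blue) lie between 4.27 and 6.47 in C6 and between 4.92 and 5.38 in F103, above all high zinc libraries (red), which reach 2.56 and 3.62.

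Whether the zinc response depended on phosphate was tested as an interaction in each accession. No single gene passed in C6 (1703 at an unadjusted p under 0.05; DESeq2 called 53) or in F103 (2246; DESeq2 called 33). In the fit without the 4 doubted libraries, edgeR called 1 gene in C6 and 0 in F103 (1460 at an unadjusted p under 0.05). Chance alone gives such a p for a share of about 0.05 of the genes tested, which were 31975 with all libraries. These counts are therefore no evidence of an interaction by themselves. In C6, the 10 genes raised by low zinc in F103, chosen at high phosphate only, responded less at low phosphate. Their mean level at low zinc was 4.65 ± 0.41 log2 CPM at low phosphate and 6.26 ± 0.18 at high phosphate (SD, n = 3 each). Their median interaction was -2.29, negative for all 10 (camera, adjusted p = 0.0065 with an estimated correlation). In F103, the 90 phosphate-responsive genes chosen in C6 stood at 4.85 ± 0.22 log2 CPM at low phosphate and low zinc and at 5.70 ± 0.15 at low phosphate and high zinc (SD, n = 3 each). This was a median zinc effect of -0.62, negative for 87 of 90 (none called; camera, adjusted p = 0.00023 with an estimated correlation). At high phosphate the median zinc effect on these genes was -0.04 (camera, adjusted p = 0.82 with an estimated correlation), and the median interaction was -0.71, negative for 74 of 90 (camera, adjusted p = 0.0047 with an estimated correlation). For the 56 zinc-responsive genes of C6 the median interaction in F103 was -0.37, or -0.44 with genes at 0 counts set to their bound. The group did not pass (camera, adjusted p = 0.24 with an estimated correlation). In counts simulated from these libraries, the edgeR test of the C6 interaction recovered 0 of 100 genes changed 2-fold and 22 of 100 changed 4-fold, so single-gene interactions of these sizes were mostly not detectable in C6. Recovery of the F103 interaction was not simulated.

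At high phosphate and high zinc, 469 genes differed between F103 and C6, of which 327 (69.7%) were higher in F103 and the others lower. Bo7g115110 was at least 364-fold higher in F103, at 37.9 ± 21.5 CPM (SD, n = 3) against 0 counts in C6 (edgeR, adjusted p = 0.005), and Bo7g056350 at least 326-fold higher, at 33.8 ± 32.9 CPM (SD, n = 3; edgeR, adjusted p = 0.026). Bo05435s010 was at least 209-fold lower in F103, where it had 0 counts against 21.3 ± 11.2 CPM (SD, n = 3) in C6 (edgeR, adjusted p = 0.017), and Bo01628s010 at least 187-fold lower, against 19 ± 13.4 CPM (SD, n = 3; edgeR, adjusted p = 0.005). In the other treatments the 327 genes kept medians of 3.14 (high phosphate, low zinc), 3.05 (low phosphate, high zinc) and 3.06 (low phosphate, low zinc), or 3.00, 3.03 and 3.00 with genes at 0 counts in a group set to their bound. Camera gave adjusted p = 0.0047, 0.019 and 0.0038 with an estimated correlation. The genes lower in F103 had medians of -1.30, -0.85 (-0.77 with genes at 0 counts in a group set to their bound) and -0.63 in the same order, with camera adjusted p = 2.2e-05, 0.01 and 0.00023 with an estimated correlation. Counts came from alignment to one reference, so a gene absent from an accession, or too different in sequence to be aligned, reads as a gene with no expression. One F103 library here had a low level of F103-only genes, and without it 941 genes were called. When all 4 doubted libraries were left out 1708 were higher and 1963 lower, including 468 of the 469. A fit of only the libraries compared called 1 gene, lower in F103, and none of the genes named here passed in it. With all libraries, leaving out 1 of the 6 compared lost the call of Bo7g056350 in 5 fits and that of Bo05435s010 in 4. On log2(FPKM + 1) 362 were higher and 267 lower (limma). Leaving out replicates 1, 2 or 3 of C6 gave 192, 92 or 68 genes. Leaving out replicate 2 of F103 gave 111, and leaving out replicate 1 gave 0.308% of the genes tested, against 1.47% with all libraries.

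The phosphate effect, averaged over zinc levels, differed between the accessions for 7 genes, 4 more positive and 3 more negative in F103. Bo9g152550 fell in C6 under low phosphate, by 4.24 ± 0.65 at low zinc and 2.91 ± 0.61 at high zinc on the log2 scale (SE; edgeR, adjusted p = 0.0022 and 0.025), while its log2 fold changes in F103 were -0.12 ± 0.54 and -0.05 ± 0.53 (SE; the difference was 3.49 ± 0.58, edgeR, adjusted p = 0.042). Bo5g025950 gave a difference of 2.18 ± 0.36 in the same direction (SE; edgeR, adjusted p = 0.042). Bo8g068450 stood at 618 ± 469 CPM in C6 at low phosphate and high zinc and at 6.11 ± 5.73 CPM at high phosphate and high zinc, against 24.0 ± 12.3 and 48.2 ± 35.7 CPM in F103 (SD, n = 3 each), a difference of -6.62 ± 0.94 in the averaged effect (SE; edgeR, adjusted p = 0.028). Bo4g111420 gave a difference of -2.55 ± 0.43 (SE; edgeR, adjusted p = 0.042). The count was 28 without the 4 doubted libraries, 5 of the 7 being among them, and Bo9g152550 did not pass (adjusted p = 0.088, edgeR). Leaving out any library but replicate 2 of F103 at high phosphate and high zinc moved it by over 1.5 times, to between 0 and 17.

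The zinc effect, averaged over phosphate levels, differed between the accessions for 1 gene. Bo2g064160 fell under low zinc in C6, from 27.1 ± 19.4 to 1.5 ± 1.11 CPM at high phosphate and from 53.6 ± 39 to 0.582 ± 0.157 CPM at low phosphate (SD, n = 3 each). In F103 it stood at 18.2 ± 13.1 and 13.5 ± 4.60 CPM at high and low zinc with high phosphate, and at 8.17 ± 0.48 and 16.2 ± 9.44 CPM with low phosphate (SD, n = 3 each). The difference in the averaged zinc effect was 5.60 ± 0.73 on the log2 scale (SE; edgeR, adjusted p = 0.0089). The gene passed in every fit that left out 1 library and in every other alternative, with adjusted p up to 0.047 (edgeR without 1 library, DESeq2 and limma). It was also the 1 gene called without the 4 doubted libraries (edgeR, adjusted p = 0.016).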

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

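The tests on gene groups and the fits without the 4 doubted libraries were chosen only after the results were seen; the single-gene interactions and the splits of the libraries were not.

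The phosphate effect differed between F103 and C6 for 7 genes by a test of the difference itself. Among 40 splits, the real one and 39 drawn at random, none of the others gave as many (1 of 40, the highest other count being 1). These splits put libraries of both accessions into 1 group, which widens the spread and holds their counts down, so they do not decide whether chance gave the 7. The differences of the genes named were 2.18 for Bo5g025950, 3.49 for Bo9g152550, -6.62 for Bo8g068450 and -2.55 for Bo4g111420 on the log2 scale. Their calls were lost in 20, 20, 13 and 22 of the 24 fits that left out 1 library, with adjusted p up to 0.12, 0.12, 0.12 and 0.13 over all alternatives (edgeR, DESeq2 and limma).

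The zinc effect differed between F103 and C6 for 1 gene, Bo2g064160, by 5.60 on the log2 scale. Of 40 splits, 2 gave a count as large; these splits mix the accessions too and decide nothing about chance. The highest other count was 1976. That split exchanged the accession labels of 8 low zinc libraries and 0 high zinc libraries, so the accession difference itself entered the contrast by construction. The call of this gene was kept in each of the 24 fits that left out 1 library.

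The zinc effect of 10 genes, raised by low zinc in F103, was smaller at low than at high phosphate in C6, with a median interaction of -2.29. The genes were chosen at high phosphate only, which may favour a larger effect there. Over all alternatives the median lay between -2.70 and -1.93.

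Genes raised by low phosphate in C6 were lower under low zinc in F103 at low phosphate, and the median interaction of the 90 genes was -0.71. The 3 F103 libraries with few F103-only transcripts are argued against as the cause. Without the 4 doubted libraries the median zinc effect at low phosphate was -0.78 (95% bootstrap interval over genes -1.04 to -0.61), with 88 of 90 genes below 0. The interval resamples genes that vary together and does not measure the spread between libraries. The mean level in the low zinc libraries left was 4.8 and 4.66 log2 CPM, against 5.58 to 5.86 at high zinc. The interaction of these genes had a camera p = 0.0026 and an adjusted p = 0.0047 with an estimated correlation. It uses the libraries in which the pattern was seen, so it restates the pattern and is no separate support for a dependence of the zinc effect on phosphate, which stays open. In C6, the 48 genes raised by low phosphate in F103 had median zinc effects of 0.30 and 0.27 at low and high phosphate. Neither passed (camera, adjusted p = 0.42 and 0.21 with an estimated correlation). Whether the accessions differ in this was not tested. What the plants took up, and how large they grew, was not analysed here.

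No single gene passed the test of whether the zinc effect depended on phosphate in C6 or F103 (edgeR), while DESeq2 called 53 and 33. In edgeR 1703 and 2246 genes had an unadjusted p under 0.05, where chance alone gives a share of about 0.05 of the 31975 tested. As both edgeR counts past the threshold were 0, all 40 of 40 splits gave a count as large by construction. The splits therefore say nothing about chance here. The highest other counts were 455 in C6, where the split exchanged the phosphate labels of 6 low zinc and 2 high zinc libraries, and 948 in F103, where it exchanged those of 2 low zinc and 0 high zinc libraries. Such uneven exchanges bring the phosphate effect itself into the contrast by construction.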

How the results depend on the processing

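The fits without the 4 doubted libraries and with 3 surrogate variables, and all alternatives for gene groups, were chosen after seeing the data. Over 13 counts and 254 alternative values, 133 lay within 1.5 times the reported count. DESeq2's size factors, the stricter filter and robust dispersion kept every count within that range. Where a count moved, the cause was not tested. Counts are given here as percent of the genes tested in each fit. Comparisons follow in this order: zinc in C6 at low and high phosphate, zinc in F103 likewise, phosphate in C6 at low and high zinc, phosphate in F103 likewise, the interaction in C6 and F103, the accessions, and the accession by phosphate and by zinc interactions. The reported values were 0.159%, 0.194%, 0%, 0.0313%, 0.629%, 0.891%, 0.166%, 0.813%, 0%, 0%, 1.47%, 0.0219% and 0.00313%, the last being 1 gene of 31975. The DESeq2 Wald test gave 3.21%, 0.465%, 0.452%, 0.184%, 1.41%, 3.59%, 0.42%, 2.48%, 0.17%, 0.12%, 4.14%, 0.363% and 0.317%; it made 36, 4 and 20 false calls where edgeR made 1, 0 and 3 in counts simulated for zinc in C6 at high phosphate, phosphate in F103 at high zinc and the C6 interaction. As those counts were drawn with edgeR's own estimates of spread, they do not show whether the further DESeq2 calls in the real data are false. The limma fit on log2(FPKM + 1) gave 0.4% for zinc in C6 at low phosphate, 0.0463% and 0.0608% for zinc in F103, 0.0029% for each interaction of zinc with phosphate and 0.00579% for the last interaction. With FPKM + 0.1 the first 3 of these were 0.634%, 0.029% and 0.055%. The limma fit on log2(FPKM + 1) differs from the reported fit in test, gene filter and pseudocount as well as in scaling. It moved the median of all genes by 0.178 for zinc in C6 at low phosphate and -0.261 for phosphate in C6 at high zinc. The shifts were 0.227 for the C6 interaction and 0.129 for the accession by phosphate interaction. All 4 comparisons hold the C6 library that lay apart. Its TMM factor was 0.721, against 0.961 to 1.07 in the others, and the FPKM fit applies no such factor. Leaving out a factor under 1 lowers a library's levels, which is the direction of all 4 shifts. The other differences between the fits were not separated. Without a filter zinc in F103 at low phosphate gave 0.0199% and the last interaction 0.00398%. With only the libraries compared, zinc in C6 at low phosphate gave 0%, zinc in F103 0.0282% and 0.00352%, phosphate in C6 at high zinc 0%, phosphate in F103 0.067% and 1.65%, and the accessions 0.00346%. Without the 4 doubted libraries the moved values were 0.00616%, 0.44%, 0.0677%, 0.00924%, 1.76%, 0.00308% (C6 interaction), 11.3% (accessions) and 0.0862% (accession by phosphate). With 3 surrogate variables they were 0.00625%, 0.679%, 0.213%, 0.159%, 2.65%, 1.89%, 0.625%, 3.22%, 0.00313% (C6 interaction), 0.4% (accession by phosphate) and 0.00625%. Leaving out 1 library gave 0% to 3.06%, 0.0915% to 0.143%, 0% to 0.0061%, 0% to 0.058%, 0.229% to 0.509%, 0.345% to 2.81%, 0.0549% to 0.162%, 0.44% to 0.671%, 0% to 0.00305%, 0% to 0.00305%, 0.208% to 2.87%, 0% to 0.052% and 0.00305% to 0.00916% in the order above. Of 35 results for named genes none reversed and 7 were past the threshold in every alternative that tested the gene, Bo3g083970 among them not having been tested in the fit of only the libraries compared; calls were lost in 46.3% of 300 values without 1 library and 10.8% of 342 others. Of 578 alternative medians of gene groups, 32 moved by more than their spread and no called one reversed. No paired analysis was possible because the replicate numbers follow the order of the samples and pair nothing across groups. The alternatives for the gene lists were not run, since no ID could be named. At depths between 8707405 and 9696889 counts, and 3 libraries per group, edgeR recovered 14 of 100 simulated 2-fold changes and 50 of 100 of 4-fold for zinc in C6 at high phosphate.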

Other observations

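The tests in this part on the F103 libraries with few F103-only transcripts, on the C6 library that lay apart, on gene groups and on neighbouring IDs were chosen only after the results were seen; the splits of the libraries were not.

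Phosphate and zinc responses met in a few genes. Of the 56 genes raised by low zinc in C6 at high phosphate, 5 were raised by low phosphate in F103 at high zinc, where independent lists would share 0.378 (Fisher's exact test, adjusted p = 5.6e-05). The 56 genes as a group had a median of -0.10 there (camera, adjusted p = 0.44 with an estimated correlation). At low zinc in F103 1 of the 56 was raised by low phosphate, where independent lists would share 0.0876 (Fisher's exact test, adjusted p = 0.11). Of the other lists, 0 of the 28 genes raised by low zinc in C6 at low phosphate was raised by low phosphate in F103 at high zinc, and 0 of the 10 raised by low zinc in F103 at high phosphate was raised by low phosphate in C6 at low or high zinc. Independent lists would share only 0.189, 0.0453 and 0.0647, so an overlap of 0 says nothing in these comparisons. The 10 genes raised by low zinc in F103 moved the other way with phosphate in C6 at low zinc: their median log2 fold change under low phosphate was -1.65, all 10 were negative and 3 were called lower (camera, adjusted p = 0.0098 with an estimated correlation). The libraries compared also entered the C6 interaction of these genes, so this restates part of that result and is no separate support. At high zinc the median was 0.50 (camera, adjusted p = 0.42 with an estimated correlation).

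The 44 genes lowered by low phosphate in F103 at high zinc had medians of -0.72 (5 called) and -0.27 (4 called) in C6 at low and high zinc, or -0.24 at high zinc with a gene at 0 counts in a group set to its bound (camera, adjusted p = 0.0039 and 0.11 with an estimated correlation). Without replicate 2 of C6 at low phosphate and low zinc the first median was -0.43. Genes with neighbouring IDs were called in the same direction more often than random sets of IDs. The accession comparison had 17 such pairs against a random mean of 3.50, and low phosphate in F103 at high zinc 10 against 1.44 (permutation p = 1e-04 for both, the smallest that 10000 draws can give). Low phosphate in C6 gave 8 against 1.48 at high zinc and 5 against 0.611 at low zinc (permutation p = 2e-04 and 3e-04).

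In 3 F103 libraries the F103-only genes stood at 0.187 (95% bootstrap interval over genes 0.157 to 0.217), 0.273 (0.225 to 0.314) and 0.271 (0.225 to 0.321) of the usual level. A C6 library with a wrong label is argued against, since the lowest ratio, 0.187, lies above the 0 of every C6 library. Another genotype that carries some of these genes and lacks others is argued against too, as at least 75.9% of the 54 genes lay within 2-fold of 1 common ratio. A candidate explanation is RNA of F103 plants mixed with RNA of plants that lack these genes, which needs such a common ratio. The shares in the 3 libraries were 75.9%, 83.3% and 79.6%, against 75.9% to 94.4% in the other 9 F103 libraries. The lowest of the 9 was replicate 2 at low phosphate and high zinc, whose median ratio of 0.863 was the lowest too. C6-only genes stood at 0.408, 0.567 and 0.498 of the C6 level in these 3 libraries and at 0 in each of the other 9. The 3 libraries thus carried C6-only transcripts, though the choice of genes low in most F103 libraries favours that 0. Whether the other part was C6 RNA alone cannot be told apart from another source, since the interval of the C6-only ratio held the value this needs in 1 of the 3 libraries.

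Replicate 3 of C6 at low phosphate and high zinc had 4470 genes at least 4-fold from the other C6 libraries, against 84 to 592 in the other libraries. A few abundant genes are argued against as the cause, since its 50 most abundant genes held 17.12% of its counts. By taking counts alone, that share is too small to shift other genes 4-fold. For the same reason the 4270 such genes left without these 50 were near certain in advance and add no support. F103 RNA is argued against by a median ratio of F103-only genes of 0. A wrong treatment label is argued against by its phosphate score of 4.51 and its zinc score of 1.94, both on the side of its label. A different mix of tissues or state of the roots may underlie it and cannot be told apart here, because 0 gene IDs could be named and no marker genes could be read. Replicate 2 of C6 at high phosphate and high zinc shifted in the same direction for 80.9% of these genes, against 29.1% to 63.9% in the other C6 libraries.

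For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real and the highest other count were 51 and 8 for zinc in C6 at low phosphate, 62 and 0 at high phosphate, and 10 and 0 for zinc in F103 at high phosphate. For zinc in F103 at low phosphate the real count was 0, so all 10 of 10 splits were as large by construction and say nothing. For phosphate they were 201 and 1 in C6 at low zinc, 53 and 0 in F103 at low zinc and 260 and 0 at high zinc, and for the accessions 469 and 0. For phosphate in C6 at high zinc they were 285 and 1164, with 2 of 10 splits as large. That split put the C6 library that lay apart with replicates 2 and 3 of the high phosphate group, which points to a structure of the samples.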
